A study of Mus musculus with 2 samples.

How the data were processed

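RNA of 3T3-L1 adipocyte-derived microvesicles (ADMs) and of the donor adipocytes was measured on 2 Agilent 2-colour 44K mouse arrays, 1 per biological replicate. Per the labels' protocols, the cells were grown with 10% fetal serum and induced with 10 µg/ml insulin, 0.25 µM dexamethasone and 0.5 mM IBMX. On day 11 the ADMs were pelleted from conditioned medium by ultracentrifugation and RNA was extracted with Trizol. From each RNA, 250 ng was amplified into labelled cRNA together with spike-in transcripts, per the labels' protocols. The labels call the replicates biological, and give no depth or RNA quality for either RNA. Both arrays sat on the same slide and were read in the same scan, so neither slide nor scan splits them. Whether the replicates were cultured, collected and extracted together is not given in the sources used here.

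Per the file headers, spot and background intensities were extracted with Feature Extraction 10.5.1.1, and the annotation is that of mouse build mm7. The mean spot intensity and the median intensity of the local background were deposited as the scanner gave them, with no normalization. The processed signals and the log10 ratio of Cy5 over Cy3 had been background-subtracted, detrended and dye-normalized by Feature Extraction, per the file headers. The deposited series table holds a log10 ratio per spot that equalled the scanner's log10 ratio on array 1 and its negative on array 2, so both columns point from cells to ADMs by the dye labels. Spot flags, as deposited, say whether a spot is well above background, saturated or an outlier, and whether its local background is an outlier. No probe carried the saturation flag in either RNA.

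Background was corrected with normexp (offset 50), ratios were normalized within each array by loess with control spots at weight 0, and the sign of array 2 was turned so that every ratio is ADM-labelled over cell-labelled. Spots with an outlier flag were left out. When this was read as the flags of the spot alone, 0 genes passed the threshold in limma (139 at an unadjusted p under 0.05); array 1 then held 13 spots with a local background above 100 scanner units, and the cause was not tested. After that result was seen, spots whose local background carries the scanner's outlier flag were left out as well, before the background correction. This removed 2566 spots of array 1 and 1942 of array 2, and left 3198 of 41174 probes without a value on 1 array or both. Results with those spots kept stand with the other alternatives. Spots of a probe were averaged, and a probe counted as well above background where at least 50% of its spots were so flagged.

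Probes were named by matching RefSeq accessions to a table of assembly GRCm38.p6, which named 23075 of 41174 probes; the other 18099 kept the file's own name. Probe coordinates are those of the files (mm7). Among the probes of a gene the one with the highest mean signal was used, and 3849 genes had more than 1 probe that passed the filter. Genes were tested where their probe was well above background in the ADM-labelled RNA on both arrays or in the cell-labelled RNA on both, which left 13186. The mean ratio of the arrays was tested against 0 with limma (3.58.1; lmFit, eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. This leaves 1 residual degree of freedom per gene, to which the moderation added 2.65 prior degrees of freedom. With median centring, used below as an alternative, the prior degrees of freedom were infinite. All genes there share a single variance, so the limma p-values of that setting do not reflect a gene's own spread and are not comparable with the main ones. A dye effect cancels in the mean of the swapped arrays but widens the spread between them. A ± value is the SD of the arrays. The offset and the background pull ratios near background towards 0, while loess then shifts them by the trend of genes of similar signal, so that the folds of genes dim in the ADM-labelled RNA can exceed those of their net signals.

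Loess assumes that genes of one brightness are on balance equal in both RNAs. Since the channels differed widely in total signal, the ratios describe the make-up of the RNAs and not amounts per RNA, and they were set beside median centring, which leaves the trend with brightness in place. With median centring the median of all tested genes was 2.34. A positive value of a single gene there is therefore not by itself above the tested genes. For genes well above background in 1 RNA on both arrays and in the other on neither, the lower bound of the fold was taken per channel after loess and Aquantile normalization, as the bright RNA's mean minus the dim RNA's mean of the higher of the probe's own value and the lowest value among probes well above background. Spike-in values are the median log2 ratio of tested genes minus that of the spike-in spots (320 of 10 probes, less those with an outlier flag), after normexp and before loess.

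The 28 gene lists were fixed before the data were examined, and 26 had at least 5 genes tested. Endothelial markers had 2, and the list of mitochondrially encoded genes had 0 because no probe matched its names. Lists were compared with all other tested genes by limma's camera with a preset correlation of 0.01, and adjusted over 26 lists. No list passed with fry, limma's rotation test of a single list, or when camera estimated the correlation between genes from the 2 arrays. That estimate has 1 residual degree of freedom. It gave a camera adjusted p of 0.895 for every list, so it cannot tell lists apart. The genes named in the text follow a rule also fixed beforehand. It takes the 10 largest changes per direction among genes past the threshold, well above background in both RNAs on both arrays and of the same sign, up to 5 bounds per direction, up to 3 members of each list, and Adipoq, Retn, Pparg, Fabp4, Lep, Cfd, Actb and Gapdh. Names that are only clone, accession or prediction identifiers were passed over for the changes and bounds. A gene that the rule takes for its bound is not reported here.

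The steps were tested on simulated arrays of 11520 genes with a known brightness trend. These had a flat background and no outlier flags, so the rates below leave out the effect of outlying local backgrounds. With channels 5 log2 units apart, 87.5% of genes changed 2-fold were recovered, and 100% of those changed 4-fold and 16-fold. Sizes came out too small there, with median estimates of 0.74, 1.45 and 2.99 for true log2 changes of 1, 2 and 4. In that simulation 12.0% of calls were unchanged genes, above the nominal 5%, and in one with equal channels 6.03% were. Both shifted sets of 30 genes were called, and 0 of 50 unshifted sets. The simulated genes varied independently, so this gives no false call rate for lists whose genes move together. The correlation estimated from the arrays was 0.52 for cytosolic ribosomal proteins and 0.76 for extracellular matrix, each from 1 residual degree of freedom. Alternatives covered the processed signals, an offset of 10, no background correction, median centring, scaling between arrays, other filters, the median of a gene's probes, the deposited series table, eBayes with a trend or robust, other thresholds, other set tests, and each replicate alone, which gives a value and no test.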

Results

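The series compared the RNA carried by microvesicles with the RNA of the cells that shed them. The cells were 3T3-L1, an established mouse line of preadipocytes that turns into fat-storing adipocytes after treatment with insulin, dexamethasone and IBMX. On day 11 after induction, adipocyte-derived microvesicles (ADMs) were collected from the conditioned medium by ultracentrifugation, and total RNA was taken from them and from the donor adipocytes. The design held 2 biological replicates, each a pair of 1 ADM RNA and 1 donor cell RNA hybridised to the same 2-colour mouse array. In replicate 1 the ADM RNA carried Cy5 and the cell RNA Cy3. In replicate 2 the dyes were exchanged. The arrays measured 41174 distinct probes under 28784 gene names, and the number of arrays limits the precision of every value below. All directions follow the dyes named in the labels, and each would turn if the RNAs had been interchanged on both arrays, so the RNAs are called ADM-labelled and cell-labelled throughout. Ratios are log2 of ADM-labelled over cell-labelled signal after loess, which sets each gene against genes of similar mean signal.

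The question of how much transcript signal each RNA gave was addressed with the spike-in transcripts, RNAs of known sequence added before labelling. Relative to the spike-ins, the genes tested gave 13.9-fold more signal in the ADM-labelled than in the cell-labelled RNA, a median log2 difference of 3.80 ± 0.22 (SD, n = 2). The difference was 3.64 in replicate 1 and 3.95 in replicate 2, so it had the same sign in both dye orientations. Its size rests on a median over unlike spike-ins, without flagged spots, so their mix can differ between arrays. Log2 Cy5 over Cy3 of the 10 spike-ins ran from -2.99 to 3.18 in replicate 1 and from 0.22 to 6.53 in replicate 2. The spike-in median used in replicate 2, ADM-labelled over cell-labelled, was -2.16, a smaller gap than that of the signals below. Gene medians (3.51 and 1.79) lay above every spike-in, but the ± 0.22 does not cover that range. With the ADM-labelled RNA in Cy5, the 99th percentile of gene probe signal was 51014 scanner units, against 677 for the cell-labelled RNA in Cy3. In the opposite orientation these percentiles were 19224 for the ADM-labelled RNA in Cy3 and 2481 for the cell-labelled RNA in Cy5. The median spike-in signal was 20876 and 23095 in replicate 1, and 5863 and 74643 in replicate 2, in the same order of RNAs. The difference was 41.1-fold when plain subtraction of local background took the place of normexp and its offset, a setting chosen after seeing the data, and 77.3-fold with the scanner's processed signals.

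Transcripts of most genes seen in the cell-labelled RNA were also seen in the ADM-labelled RNA. Of 28784 gene names, 13227 were well above background on both arrays in the ADM-labelled RNA and 8094 in the cell-labelled RNA, and 7271 in both. These 7271 genes were 89.8% of those detected in the cell-labelled RNA and 55.0% of those in the ADM-labelled RNA. In all, 2890 genes were seen on both arrays in the ADM-labelled RNA and on neither in the cell-labelled RNA, and 631 the other way round. Nid2, a basement membrane protein, was at least 2.69-fold higher in the ADM-labelled RNA, Sema3g, a secreted semaphorin, at least 2.62-fold, and Bmper, a secreted BMP-binding protein, at least 2.05-fold. The same bound was 1.94 for the succinate receptor gene Sucnr1 and 1.88 for Apod, which encodes a lipid-binding secreted protein. Higher in the cell-labelled RNA were Syt6, with a loess-scale value of 268-fold, Kif12 (189-fold), Cpb2 (116-fold) and Terc, the telomerase RNA (109.6-fold). These 4 values are no lower bounds off the loess scale, since the log2 ratios with median centring were -5.08, -4.82, -4.21 and -4.13 in that order. Except for Syt6 and Kif12, each value of this kind equals the measured ratio, as the probe's own signal in the dimmer RNA lay above the floor. In net signal without loess, Syt6 gave 939 scanner units in the cell-labelled and 18.7 in the ADM-labelled RNA of replicate 1 (3444 and 8.62 in replicate 2), Cpb2 501 and 23.8 (1978 and 9.71), Terc 524 and 23.1 (1712 and 10.8), and Nid2 11.7 and 3430 (7.39 and 1131). Leptin (Lep) was well above background only in the ADM-labelled RNA, with a log2 ratio of 0.35 ± 0.27 (SD, n = 2; limma adjusted p = 0.179), and 2.47 with median centring (adjusted p = 0.00204). Counts for the cell-labelled RNA depended on the array, with 8281 genes seen in replicate 1 alone (without replicate 2) and 12862 in replicate 2 alone (without replicate 1). Genes seen only in the ADM-labelled RNA then numbered 6773 and 3046, and those seen only in the cell-labelled RNA 754 and 2371, so presence in 1 RNA alone is a statement about signal over background in these channels.

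Across the single genes that the naming rule admits, the highest ratios in the ADM-labelled RNA, relative to genes of similar signal, began with Col6a3, Acsl1 and Hsd11b1. Col6a3, a collagen VI chain gene, had a log2 ratio of 2.83 ± 0.65 (SD, n = 2), a 7.11-fold difference. Acsl1, the fatty acyl-CoA synthetase abundant in adipocytes, stood at 2.62 ± 0.41, and Hsd11b1, which regenerates active glucocorticoid, at 2.56 ± 0.32. Ccdc80, a secreted matrix protein gene, had 2.51 and the interferon gamma receptor gene Ifngr1 2.37. Col5a1 (2.32), Col4a1 (2.27), Lrig1 (2.24), Postn (2.23) and Nid1 (2.23) completed the 10 highest, whose adjusted p ran from 0.00741 to 0.0186 in limma. The brightest probe of Col6a3 lay at chromosome 1, 90671098 to 90671157 in mouse build mm7. A second probe of Col6a3 gave 0.14 and one of Col5a1 -0.74, so these values hold for the brightest probe. With median centring the 10 ratios ran from 6.42 (Postn) to 7.87 (Acsl1).

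At the other end, the 10 lowest ratios among genes that the naming rule admits, well above background in both RNAs, ran from Creb3l3 to Phxr5. Creb3l3, a liver and gut transcription factor gene, had a log2 ratio of -10.82 ± 0.04 (SD, n = 2; limma adjusted p = 0.00102) at chromosome 10, 80876571 to 80876630 (mm7). Trim55 (-9.67 ± 0.51) and Myom3 (-8.78 ± 0.54) encode muscle proteins, and Ddx25 (-9.52 ± 0.51) a helicase of the testis. Pdpk1, a kinase of insulin signalling, had -9.74, Myo1e -8.74, Cdcp1 -8.50, Mid1 -8.11, Mast4 -8.08 and Phxr5 -8.05. Other probes of Pdpk1, Myo1e and Mast4 reached 0.59, -0.06 and -0.12, and with the median of its probes Pdpk1 turned to 0.30 (adjusted p = 0.133). These 3 values therefore belong to single probes. The sizes of all 10 depended on loess, and with median centring they ran from -6.96 (Creb3l3) to -3.83 (Phxr5), with Trim55 at -4.73 and Ddx25 at -4.64. In net signal, Trim55 gave 14982 scanner units in the cell-labelled and 2007 in the ADM-labelled RNA of replicate 1, and 32717 and 476 in replicate 2.

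In all, 2336 of 13186 genes tested passed a Benjamini-Hochberg adjusted p of 0.05 in limma, 758 of them higher and 1578 lower in the ADM-labelled RNA. The higher genes were 32.4% of these calls, 62.2% with the scanner's processed signals (3712 higher, 2257 lower) and 97.3% with median centring in place of loess (8194 higher, 225 lower). These settings set the median of all tested genes at 0.51 and 2.34 in place of 0.04. With spots of outlying local background kept, a setting added after seeing the data, limma called 0 genes, and 139 had an unadjusted p under 0.05, against 5058 otherwise. On both arrays, 173 genes were at least 2-fold higher and 1060 at least 2-fold lower, and without replicate 1 the same rule gave 392 and 1799. The arrays agreed across genes with a Pearson r of 0.932 and a Spearman rho of 0.846 over the tested genes, which are not independent replicates. The sign was the same on both arrays in 82.5% of genes, against 50.2% for independent arrays. Across the 6662 genes well above background in both RNAs, log2 net signals of the ADM-labelled RNA correlated at 0.996 between arrays and those of the cell-labelled RNA at 0.979. Among genes named below, other probes of Col1a1, Klf15, Cavin1, Anxa4, Eif5a and Akt1 gave log2 ratios of 0.06, -0.20, 0.0069, 0.07, 0.35 and -0.51, apart from the values of their brightest probes. With the median of a gene's probes Klf15, Cavin1, Eif5a, Mast4 and Actb did not pass in limma (adjusted p from 0.0681 to 0.347). With the scanner's processed signals Apoe, Plin1, Thrsp, Mrpl3, Mrps15, Cox8b, Ybx1 and Actb did not (0.0501 to 0.939), and with no filter Cd74 and Lyz1 did not (0.0546 and 0.0517). A trended eBayes ended the calls of Lpl, Plin1, Thrsp, Rpl12 and Rps12 (0.12 to 0.25), a robust one those of Mrps15, Ifit1, Cd74 and Lyz1 (0.0508 to 0.0534), and an offset of 10 those of Plin1 and Mrps15 (0.0633 and 0.0542). Within an array, the ADM-labelled and cell-labelled signals correlated at 0.585 and 0.632 over the same genes.

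**Figure D1:**
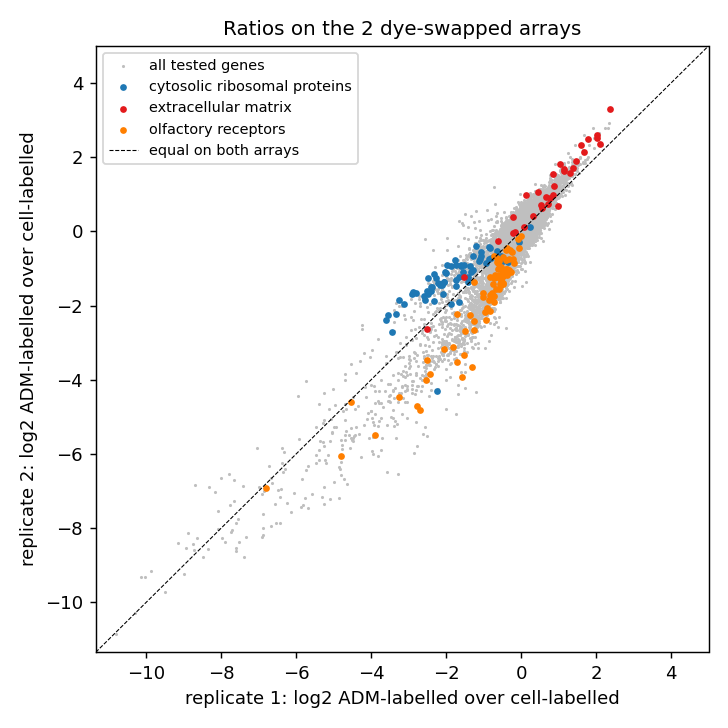
Log2 ADM-labelled over cell-labelled ratio of each tested gene (grey points) in replicate 1 (x axis) and replicate 2 (y axis), with 3 gene lists in colour and a dashed line of equal values. Values of the arrays follow each other (Pearson r 0.932). Extracellular matrix genes lie mostly above 0, and cytosolic ribosomal protein and olfactory receptor genes mostly below, though the ribosomal list turns to the higher side with median centring in place of loess. Olfactory receptor genes passed the filter mostly through the cell-labelled RNA, which favours that side.

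Matrix genes were the list furthest to the ADM-labelled side. Of 32 extracellular matrix genes tested, 22 were higher, 2 lower and 8 did not pass, with a median log2 ratio of 0.88 and 24 higher and 3 lower when adjusted over the list alone (camera adjusted p = 6.14e-07; adjusted p = 0.895 with an estimated correlation). The list's median against all tested genes was 0.84, and it moved to 0.28 with outlying local backgrounds kept, 1.64 with the processed signals and 2.34 with median centring, passing the set test in each. Timp1, an inhibitor of matrix-degrading proteases, went the other way at -2.57 ± 0.07 (SD, n = 2), although another of its probes gave 0.05 and median centring 1.23. Of 21 preadipocyte and fibroblast markers, 9 were higher and 1 lower (9 and 1 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.00113; adjusted p = 0.895 with an estimated correlation). The 9 included Postn and Col1a1 (2.14 ± 0.48), and the lower one was Tagln (-2.56 ± 0.19), a smooth muscle and fibroblast actin-binding protein gene that stood at 0.97 with median centring. Against all tested genes this list's median of 0.31 moved to 0.14, 1.60 and 1.97 under the same 3 settings, and passed in each. Each of these lists had 8 members that also stood in another list.

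The list of fat synthesis genes also passed the set test on the ADM-labelled side. Of 21 genes of fatty acid and triglyceride synthesis, 6 were higher, 1 lower and 14 did not pass, with a median of 0.46 (camera adjusted p = 0.00475; adjusted p = 0.895 with an estimated correlation; 8 higher and 1 lower adjusted over the list alone). Dgat1, which makes triglycerides, stood at 1.33 ± 0.01 (SD, n = 2), and Thrsp, a regulator of fat synthesis, at -1.42 ± 0.56, or 3.97 with median centring. The list's test missed its threshold with the scanner's processed signals (adjusted p = 0.0854). The list also missed it with outlying local backgrounds kept, where its median against all tested genes went from 0.41 to 0.17 (adjusted p = 0.213). The lists of adipogenic transcription factors, lipid droplet genes and adipokines did not pass the set test after loess, but did with median centring, at medians of 1.54, 1.85 and 0.64 against all tested genes (camera adjusted p = 0.00134, 8.08e-05 and 0.0272). Adipogenic transcription factors had 3 higher, 1 lower and 16 that did not pass (3 and 1 adjusted over the list alone; camera adjusted p = 0.315). Srebf1, a master regulator of lipid synthesis, was at 1.57 ± 0.25, Klf15 at 0.88 ± 0.03 and Ppargc1b at 0.88 ± 0.22. Pparg, the master regulator of adipogenesis, had -0.28 ± 0.25 (adjusted p = 0.241 in limma). With median centring Pparg turned to 4.64 (limma adjusted p = 1.16e-08, from a variance shared by all genes). Lipid droplet and lipolysis genes had 3 higher and 3 lower of 17 (3 and 4 adjusted over the list alone; camera adjusted p = 0.727). Fitm2 (1.52 ± 0.18), which partitions fat into droplets, and the caveola coat gene Cavin1 (1.21 ± 0.30) were higher, and the droplet coat gene Plin1 lower (-1.33 ± 0.47; 4.19 with median centring).

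Adipokines and other secreted adipocyte proteins had 1 higher, 1 lower and 10 that did not pass of 12 (2 and 2 adjusted over the list alone; camera adjusted p = 0.727), with a median of 0.06 and a mean of -0.14. Apoe had 0.77 ± 0.0022 (SD, n = 2) and Lpl, the lipase that releases fatty acids from lipoproteins, -2.75 ± 0.90, or 2.97 with median centring. The brightest probe of resistin (Retn) gave -1.16 ± 0.55 (adjusted p = 0.0511 in limma), and its other probe 0.52 and 0.92 on the 2 arrays. Fabp4, the fatty acid carrier of adipocytes, had -0.59 ± 0.13 (adjusted p = 0.0520 in limma), and with median centring 5.37. Another Fabp4 probe, with an outlier flag in replicate 1, gave 0.75 in replicate 2, against -0.68 for the brightest probe there. Adiponectin (Adipoq) and adipsin (Cfd) had an outlier flag in replicate 1 and were not tested, and in replicate 2 they gave 1.03 and 1.11. Insulin signalling and glucose uptake genes had 3 higher and 4 lower of 17 (5 and 5 adjusted over the list alone; camera adjusted p = 0.841), among them the insulin-responsive glucose transporter Slc2a4 at 1.39 ± 0.21 and Akt1 at -2.21 ± 0.07. Akt1 stood at 2.28 with median centring. Angiogenic factors had 2 higher and 4 lower of 22 (2 and 5 adjusted over the list alone; camera adjusted p = 0.841), the median being 0.05 and the mean -0.34. Fgf2 was lower (-3.33 ± 0.50), as were Vegfb (-2.65 ± 0.10) and Vegfa (-2.78 ± 0.46). Other probes of these 3 genes reached 0.22, 0.05 and 0.57, and both Vegf genes turned positive with median centring (2.56 and 1.34). Of 27 genes of extracellular vesicle proteins, 3 were higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.0528), namely Lamp2 (1.25 ± 0.01) and the caveolin gene Cav1 (0.90 ± 0.03) among the higher and Anxa4 (-2.12 ± 0.08, or 1.87 with median centring) the lower one. This list's median against all tested genes was 0.16, and its set test passed under 8 alternatives, from an adjusted p of 0.000109 with median centring to 0.0468 with scaling between arrays.

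Cytosolic ribosomal protein messages lay mostly on the cell-labelled side, a direction that held with the scanner's processed signals and turned with median centring (their median against all tested genes was -1.58, -1.24 and 1.14 in that order). Of 66 cytosolic ribosomal protein genes, 55 were lower in the ADM-labelled RNA, 0 higher and 11 did not pass (64 lower adjusted over the list alone), with a median of -1.54 (camera adjusted p = 1.15e-19; adjusted p = 0.895 with an estimated correlation). Rpl14 had -3.27 ± 1.46 (SD, n = 2), Rpl12 -3.07 ± 0.53 and Rps12 -2.99 ± 0.85. Multigene families such as this one have many processed pseudogenes, which the probes may not tell apart. Translation factors had 14 lower and 0 higher of 70 (18 and 0 adjusted over the list alone; camera adjusted p = 0.0202; adjusted p = 0.895 with an estimated correlation), with Eif4ebp2 at -2.10 ± 0.09 and Eif5a at -1.88 ± 0.33. This list also turned with median centring (1.19 against all tested genes), as did Eif4ebp2 (2.12) and Eif5a (2.67), and missed its threshold with the processed signals (camera adjusted p = 0.138) and with outlying local backgrounds kept, where its median against all tested genes went from -0.21 to -0.0051 (0.235). The 72 mitochondrial ribosomal protein genes had 3 higher, 1 lower and 68 that did not pass (0 and 1 adjusted over the list alone), and a median of 0.22 (camera adjusted p = 0.00792; adjusted p = 0.895 with an estimated correlation). Their median against all tested genes was 0.18, but -0.20 with the processed signals (camera adjusted p = 0.342). Mrpl3 (0.68 ± 0.07) and Mrps15 (0.62 ± 0.12) were higher and Mrpl57 lower (-1.63 ± 0.18; 3.24 with median centring). Nuclear-encoded oxidative phosphorylation genes had 6 higher and 5 lower of 58 (16 and 10 adjusted over the list alone; camera adjusted p = 0.669), from Sdha at 1.43 ± 0.20 to Cox8b at -1.26 ± 0.33 and Atp5k at -3.44 ± 1.13, the last 2 positive with median centring (3.61 and 1.90). This list passed the set test with median centring (2.33 against all tested genes; camera adjusted p = 6.31e-15) and an offset of 10 (0.31; 0.0259), and passed in the other direction with outlying local backgrounds kept (-0.079; 0.000783). Proteasome subunits had 4 higher and 2 lower of 34 (4 and 3 adjusted over the list alone; camera adjusted p = 0.315), including Psma1 (0.89 ± 0.20), Psma3 (0.80 ± 0.03) and Psme3 (-1.49 ± 0.13; 2.41 with median centring), and passed the set test with median centring (2.02 against all tested genes; camera adjusted p = 7.59e-08).

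**Figure D2:**
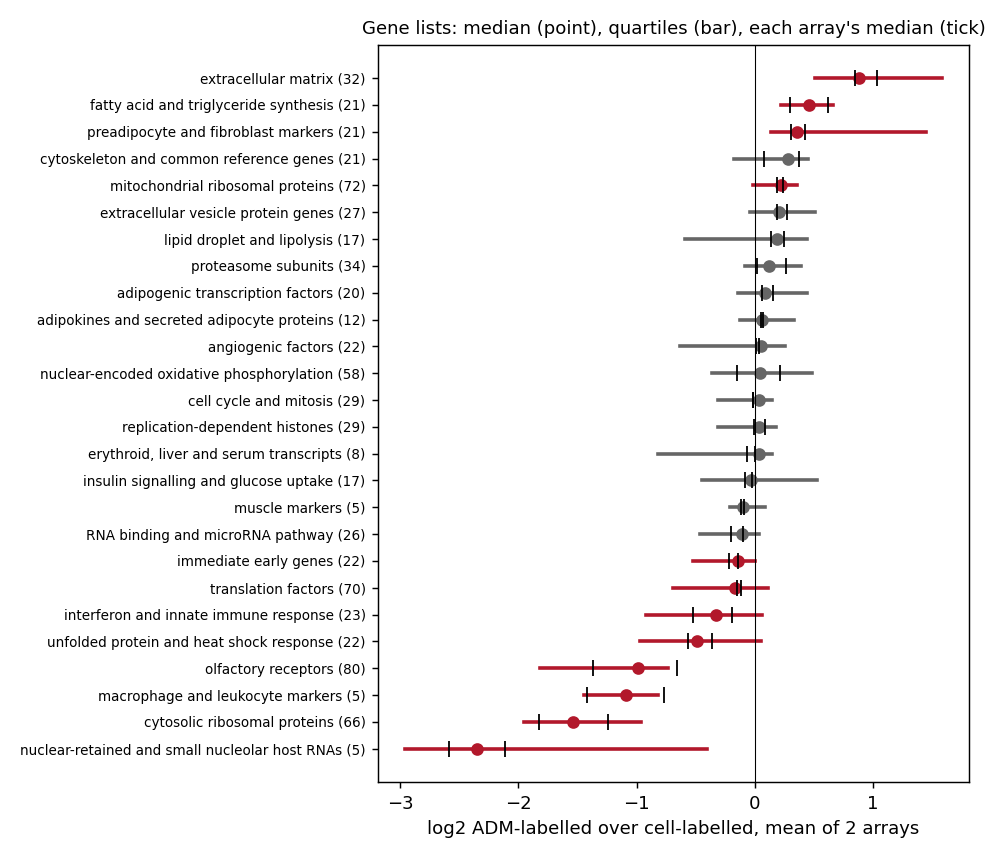
Median log2 ADM-labelled over cell-labelled ratio of each of the 26 gene lists (points; number of genes tested in parentheses), with the quartiles of its genes (bars) and the median on each array (ticks); red marks a camera adjusted p under 0.05. The median runs from -2.35 for nuclear-retained and small nucleolar host RNAs to 0.88 for extracellular matrix. Of the lists past the threshold in either setting, those of cytosolic ribosomal proteins, translation factors, histones and the unfolded protein response turn to the higher side with median centring.

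Among the 5 nuclear-retained or small nucleolar host RNAs tested, of 12 on the array, 3 were lower and 0 higher (4 and 0 adjusted over the list alone), with a median of -2.35 (camera adjusted p = 0.0151; adjusted p = 0.895 with an estimated correlation). Gas5, a host of small nucleolar RNAs, had -2.96 ± 0.16 (SD, n = 2) and Rmrp, the RNA of a mitochondrial and nucleolar RNase, -2.35 ± 0.34, and both were positive with median centring (1.63 and 1.21). Another probe of Gas5 gave -0.86. The list's median against all tested genes went from -2.39 to -0.17 with no filter on background (camera adjusted p = 0.0151), and to -1.13 with median centring, where the set test missed its threshold (camera adjusted p = 0.0747). It also missed it with outlying local backgrounds kept (-0.50; 0.235). Unfolded protein and heat shock genes had 7 lower and 2 higher of 22 (11 and 3 adjusted over the list alone; camera adjusted p = 0.0251; adjusted p = 0.895 with an estimated correlation), and turned as a list with median centring (1.44 against all tested genes). The chaperone genes Calr (-2.63 ± 0.34), Hsph1 (-2.24 ± 0.14) and Hsp90aa1 (-1.61 ± 0.39) were among the lower, although a second probe of Calr gave 0.44 and all 3 were positive with median centring. Immediate early genes had 5 lower and 0 higher of 22 (5 and 0 adjusted over the list alone; camera adjusted p = 0.0459; adjusted p = 0.895 with an estimated correlation), from Junb (-5.16 ± 0.66) to Jund (-1.85 ± 0.34) and Atf3 (-1.60 ± 0.62), the last 2 positive with median centring. Another probe of Junb gave -1.18, and with median centring Junb stood at -0.87 and did not pass (limma adjusted p = 0.312). Interferon and innate immune genes had 3 lower and 0 higher of 23 (9 and 0 adjusted over the list alone; camera adjusted p = 0.0427; adjusted p = 0.895 with an estimated correlation), namely the chemokine genes Ccl5 (-4.79 ± 0.07) and Cxcl10 (-1.68 ± 0.55) and Ifit1 (-1.26 ± 0.53), the last 2 again positive with median centring, where Ccl5 did not pass (-0.90; limma adjusted p = 0.296). With the processed signals the set tests of the unfolded protein, immediate early and interferon lists missed their threshold (camera adjusted p = 0.0547, 0.106 and 0.138), and with median centring those of the immediate early and interferon lists did (0.664 and 0.557). All 3 also missed it with outlying local backgrounds kept (0.0563 each) and for genes in both RNAs (0.165, 0.123 and 0.0525), the unfolded protein list with an offset of 10 (0.0637), the immediate early list with no filter (0.0515) and the interferon list with no background correction (0.0559). RNA-binding and microRNA pathway genes had 2 lower and 0 higher of 26 (2 and 0 adjusted over the list alone; camera adjusted p = 0.152), which were Ddx6 (-2.51 ± 0.21) and Ybx1 (-1.18 ± 0.33), both positive with median centring. Replication-dependent histones had 3 lower and 0 higher of 29 (1 and 0 adjusted over the list alone; camera adjusted p = 0.727; median 0.04, mean -0.13), and turned as a list with median centring (1.30 against all tested genes; camera adjusted p = 0.0481). None of 29 cell cycle genes passed in limma (camera adjusted p = 0.841).

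Few messages of cell types other than adipocytes had signal enough to be tested. Only 80 of 908 olfactory receptor genes, which are expressed by nasal sensory neurons, passed the filter, and 31 of them were lower in the ADM-labelled RNA and 0 higher (73 and 0 adjusted over the list alone). Their median was -0.99 (camera adjusted p = 1.16e-17; adjusted p = 0.895 with an estimated correlation), and Olfr744 at chromosome 14, 45952716 to 45952775 (mm7), had -6.86 ± 0.09 (SD, n = 2). Olfr430 (-5.42 ± 0.89) and Olfr1153 (-4.68 ± 1.13) followed. Among the probes of this family, 75 were well above background on both arrays in the cell-labelled RNA and 33 in the ADM-labelled RNA. Genes that pass the filter through the cell-labelled RNA lean to its side by selection, so the filter partly sets this list's direction and p-value. With no filter the list's median against all tested genes was -0.052, in place of -1.03 (camera adjusted p = 0.000521). It was -0.071 with outlying local backgrounds kept, -4.34 with the processed signals and -2.86 with median centring. Of 5 macrophage and leukocyte markers tested, of 19 on the array, Cd74 (-3.93 ± 1.91) and Lyz1 (-1.09 ± 0.46) were lower and 0 higher (4 and 0 adjusted over the list alone; camera adjusted p = 0.0459; adjusted p = 0.895 with an estimated correlation), Lyz1 being positive with median centring (1.57). With no filter this list's median against all tested genes went from -1.14 to -0.041 and its set test missed the threshold (camera adjusted p = 0.107), as it did with outlying local backgrounds kept (-0.036; 0.0563). It stood at -3.22 with the processed signals and -2.63 with median centring. None of 5 muscle markers passed in limma (camera adjusted p = 0.727), and of 8 erythroid, liver and serum transcripts only Hbb-y did (-2.58 ± 0.57; camera adjusted p = 0.727). With median centring Hbb-y stood at -1.46 and did not pass (limma adjusted p = 0.0769), while its list passed the set test (-2.04 against all tested genes; camera adjusted p = 0.0481). Of the endothelial markers, 2 genes had signal enough, Esam with -0.33 ± 0.30 and Flt1 with 0.03 ± 0.01, neither past the threshold in limma, though Flt1 passed with median centring (2.54; adjusted p = 0.00151).

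Of 21 cytoskeleton and reference genes, 3 were higher, 3 lower and 15 did not pass (7 and 4 adjusted over the list alone; camera adjusted p = 0.177), among them B2m at 1.19 ± 0.27 (SD, n = 2) and Polr2a at -2.22 ± 0.97. Polr2a did not pass with median centring (-0.93; limma adjusted p = 0.278). The list's set test passed with median centring (2.10 against all tested genes; camera adjusted p = 3.05e-05) and with no filter (0.29; 0.0380). The brightest Actb probe, which the files place on chromosome X, gave -0.69 ± 0.01 (adjusted p = 0.0364 in limma) and the other Actb probe 0.41 and 0.36 on the 2 arrays. The brightest Gapdh probe, which the files name MGC68323 and place on chromosome 1, had -1.14 ± 0.68 (adjusted p = 0.0674 in limma). The other Gapdh probe gave -2.29 and -1.37 on the 2 arrays. Whether these probes measure Actb and Gapdh alone was not tested. With median centring, the brightest probes of Actb and Gapdh stood at 3.70 and 4.10.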

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

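Control spots printed by the array maker lie outside the gene comparison, and 7 sets of them gave signal above every one of 153 negative control spots in both RNAs on both arrays. Their names read as 3' and 5' probes of mouse transcripts coded AB, GD, PC and RR, which the files do not explain. In net signal without normalization, the log2 ratio of ADM-labelled over cell-labelled RNA was 4.80 ± 2.42 (SD, n = 2) for the AB 3' spots and 4.71 ± 2.23 for the AB 5' spots. It was 3.91 ± 2.32 for GD 3', 4.22 ± 1.61 for GD 5', 6.84 ± 2.33 for PC 3', 3.67 ± 2.37 for RR 3' and 3.17 ± 2.25 for RR 5'. In each set the ratio was higher in replicate 1, without replicate 2, than in replicate 2, without replicate 1. In that order it was 6.51 and 3.09 for AB 3', 6.29 and 3.13 for AB 5', 5.55 and 2.26 for GD 3', 5.36 and 3.08 for GD 5', 8.49 and 5.19 for PC 3', 5.35 and 2.00 for RR 3', and 4.76 and 1.58 for RR 5'. Median spike-in signal moved the same way, from 20876 (ADM-labelled) and 23095 (cell-labelled) in replicate 1 to 5863 and 74643 in replicate 2. These ratios and their SDs therefore hold the channel scale of each array and are no measure of replicate spread. The signal of AB at the 3' spots was 6.72 times that at the 5' spots in the ADM-labelled RNA and 5.76 times in the cell-labelled RNA of replicate 1, and 6.86 and 7.06 times in replicate 2. For GD the same factors were 15.7 and 13.8, then 13.1 and 23.1, and for RR 0.95 and 0.63, then 0.89 and 0.67, so that of RR was higher in the ADM-labelled RNA on both arrays. The PC 5' spots did not exceed the negative controls in the cell-labelled RNA, so no factor is given for PC. No explanation of the sign of the ratios or of the 3' to 5' factors was tested.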

How the results depend on the processing

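The alternative with spots of outlying local background kept, and the spike-in value with no offset, were chosen after seeing the data. Signal over background in the cell-labelled channel, a single residual degree of freedom, the normalization and the handling of outlying local backgrounds limit these results. Leaving out saturated probes removed nothing, and the series table repeats the processed signals. Without these and without lone arrays, which have no test, single genes kept their sign and their side of the threshold in 957 of 1167 comparisons with an alternative, and lists, by the sign of their median against all tested genes, in 215 of 308.

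Genes past the threshold numbered 5969 with the processed signals (3712 higher) and likewise 5969 and 3712 with the series table, 4196 with an offset of 10 (1520 and 2676 lower), 3984 without background correction (1367 and 2617), 8419 with median centring (8194 and 225), 3812 with scaling between arrays (1383 and 2429), 3525 with a trended eBayes (1438 higher), 4332 at an adjusted p of 0.1 (1645 and 2687), 1451 with a 2-fold minimum (262 higher), and 0 with outlying backgrounds kept (0 higher, 0 lower). Of 2336 genes called, 2049 were also called with the processed signals, 2 turned sign there, and 863 turned with median centring. These signs are taken against 0, while the median of all tested genes was 2.34 with median centring. At least 2-fold apart on both arrays were 3600 higher and 2133 lower with the processed signals and with the series table, 432 and 1938 with an offset of 10, 267 higher without background correction, 8454 and 256 with median centring, and 0 and 149 with outlying backgrounds kept. A 1.5-fold limit gave 657 and 1842, and a 4-fold limit 9 and 430. A lone array gave 179 to 392 higher and 1219 to 1799 lower. The Pearson r was 0.925 with the processed signals and with the series table, 0.943 without background correction, 0.956 with median centring, 0.911 without a filter, 0.942 for genes in both RNAs and 0.754 with outlying backgrounds kept.

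Of 26 lists, 12 passed. This became 6 with the processed signals or the series table, 7 for genes in both RNAs, 7 with outlying backgrounds kept, 18 with median centring, 12 to 13 with an offset of 10, no background correction, scaling, no filter, the median of a gene's probes or ranks, and 0 with fry or with camera at an estimated correlation. The estimated correlation gave every list the same adjusted p, from 1 residual degree of freedom, so it cannot tell lists apart. Turned below means a change of sign where the main or the alternative setting passed the threshold. Lists are taken against all tested genes, but single genes against 0. With median centring the median of all tested genes was 2.34, so the genes listed under 2.34 still lay below it. With median centring the lists of cytosolic ribosomal proteins (1.14), translation factors (1.19), histones (1.30) and the unfolded protein response (1.44) turned. Oxidative phosphorylation, not called, turned with outlying backgrounds kept (-0.079). Single genes that turned with median centring were Lpl 2.97, Retn 4.04, Plin1 4.19, Thrsp 3.97, Akt1 2.28, Tagln 0.97, Timp1 1.23, Vegfa 1.34, Vegfb 2.56, Anxa4 1.87, Rpl14 0.10, Rpl12 2.69, Rps12 2.85, Mrpl57 3.24, Eif4ebp2 2.12, Eif5a 2.67, Atp5k 1.90, Cox8b 3.61, Psme3 2.41, Hist3h2a 1.26, H4c1 3.11, H2ac10 2.55, Gas5 1.63, Rmrp 1.21, Jund 2.88, Atf3 1.14, Calr 2.40, Hsph1 2.13, Hsp90aa1 3.30, Cxcl10 1.28, Ifit1 0.90, Ddx6 0.30, Ybx1 3.58, Pabpc1 3.68, Lyz1 1.57, Acta1 1.70, Pparg 4.64, Fabp4 5.37, Actb 3.70, Gapdh 4.10. With the median of a gene's probes Pdpk1 (0.30) and Vegfa (0.48) turned, and with outlying backgrounds kept Cavin1 (-0.50) and Vegfa (0.30). By construction median centring leaves the brightness trend in place; the cause of the other changes was not tested.

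With the weaker detection flag, 14059 genes were seen in the cell-labelled RNA, 12204 in both, 1547 only in the ADM-labelled and 985 only in the cell-labelled RNA. Detection on at least 1 array gave 13049 in the cell-labelled RNA, 10936 in both and 2113 only in the cell-labelled RNA. A lone array gave 8281 to 12862 in the cell-labelled RNA, 3046 to 6773 only in the ADM-labelled and 754 to 2371 only in the cell-labelled RNA. The log2 excess over spike-ins was 6.27 with the processed signals, 4.95 for genes in both RNAs and 5.36 with no offset. The ratio within each array is itself the paired comparison of a replicate's RNAs. A single array gives no test, so counts past a threshold, the agreement of the arrays and the set tests have no value without a replicate.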

Other observations

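All tests below were chosen after the result was seen, except that of the membrane protein families. Probes that the files place on the mitochondrial chromosome, whose genes were in no list that could be tested, lay on the cell-labelled side after loess. The probes at positions 11370 to 11429, 11419 to 11475 and 15099 to 15158 of chromosome M (mm7) had log2 ratios of -7.59 ± 0.82, -7.61 ± 1.00 and -7.77 ± 1.32 (SD, n = 2), with limma adjusted p of 0.00519, 0.00716 and 0.0102. In net signal without loess the direction differed between the arrays, but net signals hold the channel scale of each array. Median spike-in signal moved the same way, from 20876 (ADM-labelled) and 23095 (cell-labelled) in replicate 1 to 5863 and 74643 in replicate 2. The change of direction is therefore no measure of replicate spread. The probe at 15099 gave 106686 scanner units in the ADM-labelled and 62971 in the cell-labelled RNA of replicate 1, and 26003 and 191790 in replicate 2, and the other 2 probes were also brighter in the ADM-labelled RNA of replicate 1 (49666 against 33677, and 60727 against 34703). Genes named for zinc fingers (Zfp), taken from their names after the data were seen, had 23 lower and 1 higher of 226, with a median of 0.01, at percentile 20.4 of 10000 random lists matched on signal. Rab genes had 3 lower and 2 higher of 50. Where the most 5' and most 3' probes of a gene could be compared, they lay over 1 log2 unit apart, in the same direction on both arrays, in 151 of 918 genes.

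The excess of gene over spike-in signal in the ADM-labelled RNA was weighed against 3 technical explanations. A dye or scanner difference would change sign with the dyes, but the smaller of the per-array values was 3.64 against an SD of 0.22, which argues against it. That SD leaves out the differences between spike-ins, although the sign held against each of them on both arrays. More broken RNA in the cell-labelled sample would lower its signal at probes far from the 3' end, where labelling starts. Yet among probes well above background in both RNAs on both arrays, the most 5' one had the higher ratio in 48.0% of 918 genes (Wilson 95% interval 44.8 to 51.3). The share was 46.1% in 592 genes with end probes further apart (42.1 to 50.1) and 51.5% in 326 with closer ones (46.1 to 56.9). In the 151 genes whose end probes differed by over 1 log2 unit it was 37.7% (30.4 to 45.7). There the 3' probe more often had the higher ratio, opposite to this explanation, and the cause was not tested. Probes lost from the cell-labelled RNA were not counted, and distances run along the genome. These shares therefore speak for the probes kept and do not exclude broken RNA. Interchanged RNA names on both arrays cannot be told apart from true labels, because the lists that bear on it point apart. Matrix messages, translated at the endoplasmic reticulum of cells, lay on the ADM-labelled side. Nuclear-retained or small nucleolar host RNAs lay on the cell-labelled side (median -2.39 against all tested genes over 5 members that passed the filter, and -0.17 with no filter). The 3 members called were Terc, Gas5 (a small nucleolar RNA host) and Rmrp (mitochondrial and nucleolar), so the list is no clean gauge of nuclear retention. A difference in messenger content per mass of total RNA, between vesicles and cells, also stays open and was not tested.

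Low ribosomal protein and high matrix messages in the ADM-labelled RNA were weighed next. A brightness trend left by the normalization is argued against as the whole cause. The ribosomal median of -1.54 lay below all 10000 matched lists (central 95% from -0.73 to -0.18) and the matrix median of 0.88 above all of them (-0.27 to 0.20). Lists matched to the ribosomal genes centred on -0.41, so part of the ribosomal shift went with brightness. The matched lists drew genes singly, while the ribosomal genes had a correlation of 0.52, estimated from 1 residual degree of freedom, so the ranges leave that out. The direction of the ribosomal list also rests on loess or on the scanner's own dye normalization (1.14 against all genes with median centring). Loss of long messages in the cell-labelled sample would leave other short messages as low, but mitochondrial ribosomal and oxidative phosphorylation genes had a pooled median of 0.17 over 130 genes. A candidate explanation is that messages translated at the endoplasmic reticulum are the richer ones in the ADM-labelled RNA: 345 genes of the families Slc (without Slc25), Tmem, Itg, Sema, Ptpr and Tspan had a pooled median of 0.15, above all 10000 matched lists (0.0039 to 0.091). The size was small, 42 of these genes were higher and 38 lower, Itg and Ptpr had medians of -0.08 and -0.24, and the mitochondrial families Slc25, Timm and Tomm reached 0.12 (percentile 92.2), so this remains a hypothesis that interchanged labels would turn round.

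Signal at olfactory receptor probes in the cell-labelled RNA was weighed last. Random noise near background is argued against, as 75 of 952 probes were well above background on both arrays, in opposite dyes, where independent draws give 20.1. Genomic DNA labelled evenly along the genome would reach most of these probes, but 25.9% exceeded the 95th percentile of negative controls on both arrays (Wilson 95% interval 23.3 to 28.8), against 11.2% in the ADM-labelled RNA. The arrays differed, as the median cell-labelled signal of these probes was 8 against a percentile of 10.4 in replicate 1, and 8.55 against 7.64 in replicate 2. Most probes thus exceeded it in replicate 2, and even labelling of DNA is not excluded. Binding of other RNAs to these probes, DNA labelled unevenly and true transcription stay open and were not tested, as the probe sequences were not used here.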
